A study of Rattus norvegicus with 8 samples.

How the data were processed

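Fetal testis RNA from 8 samples, 4 from vehicle-exposed and 4 from DBP-exposed dams, had been hybridised to Affymetrix rat expression arrays, 1 array per sample. Per the labels, the dose was 50 mg/kg, given daily from gestational day 12 to 20, and tissue was taken 6 h later. The deposited values are log2 signals that the authors made with RMA, per the submitters' processing notes, with 1 value per probe set and array; the RMA version is not given in the sources used here. The raw array files were not used here. The table held 31099 probe sets, of which 57 Affymetrix controls were set aside and 31042 tested. The values were checked to be on the log2 scale, 0 pairs of arrays were identical, and each array column matched 1 sample. Array medians were 6.08 to 6.13, correlations were 0.998 within the vehicle group and 0.992 to 0.997 within the DBP group.

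Probe sets were named from the platform's gene table. 20826 had 1 gene symbol, 436 had several and 9780 had none; the last 2 kinds were tested but not named. Where a gene had several probe sets, that with the highest mean over all 8 arrays represented it, which gave 14217 genes. No genome coordinates were used here. The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The groups were compared with limma (version 3.58.1, R 4.3.3; linear model and empirical Bayes moderation without trend or robust options), 2-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Every adjusted p of a gene comes from this model unless a list alone is named, in which case the adjustment ran over that list's measured members. Confidence intervals are 95% intervals of the same model. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.

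The genes named in the report were the 12 with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, up to 4 members of each list with the smallest unadjusted p, and a fixed set of steroidogenic and marker genes. Of that set, Hmgcs1 and Ddx4 were not analysed here, since no single-symbol probe set carried their names. The named genes numbered 106. Other genes are said to have been chosen after their values were seen.

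The 20 gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Camera gave an unadjusted p under 0.05 for 4 lists and 2 passed. With an estimated correlation 0 lists had an unadjusted p under 0.05 and 0 passed, and with fry's directional test 5 had and 0 passed. Fry's test that ignores direction passed for most lists, such as steroidogenesis (adjusted p = 1.6e-05) and Leydig cell markers (0.000113). It did not pass for cholesterol synthesis (0.238), germ cells (0.149), myoid cells (0.107), stroma (0.0509), erythroid cells (0.181) and mesonephric duct (0.116). That test asks whether members of a list changed at all, without regard to the other genes. In limma 5664 of 31042 probe sets had an unadjusted p under 0.05, so passing it says little about a particular list. The adjusted p of camera, with the median log2 change, was 0.316 (0.10) for steroidogenesis, 0.278 (-0.02) for Leydig cell markers, 0.961 (0.02) for cholesterol synthesis, 0.52 (0.00) for cholesterol uptake, 0.278 (-0.08) for fatty acid synthesis, 0.84 (0.00) for fatty acid oxidation and PPAR alpha response, 0.263 (-0.07) for steroidogenic regulators, 0.988 (0.02) for immediate early genes, 0.674 (0.06) for heat shock and 0.448 (0.06) for xenobiotic metabolism. It was 0.0471 (-0.04) for cell cycle, 0.674 (0.03) for Sertoli cells, 0.84 (0.02) for germ cells, 0.263 (0.14) for myoid cells, 0.0433 (-0.13) for stroma, 0.382 (0.07) for endothelium, 0.0616 (0.11) for macrophages, 0.219 (0.22) for erythroid cells, 0.674 (0.06) for mesonephric duct and 0.797 (0.03) for adrenal markers.

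The procedure was tested on simulated data of 31042 probe sets with the spread of the real arrays, 200 of them changed (seed 1), for DBP against vehicle. It called 100 of 100 probe sets changed by a log2 of 1 and 91 of 100 changed by 0.5, with 5 false calls and 0 of the wrong sign. Camera called 10 of 10 simulated lists of 20 genes shifted by 0.3 and 0 of 10 unshifted ones. The simulated probe sets varied independently of each other, with the same spread in both groups and no batch. The simulation therefore does not show how camera behaves where genes vary together, as they may on the real arrays.

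The alternatives were filters on signal (a mean log2 above the median, 15520 probe sets, or above 5, 19928 probe sets), shifting arrays to the same median, quantile normalization, a trend and robust prior, the replicate number as a block, the RNA integrity number as covariate, array weights, leaving out cross-matching probe sets, leaving out each array in turn, other thresholds, unmoderated t statistics, 1 probe set per gene, the mean over a gene's probe sets, and the other list tests. Chosen after the spike-in signals were seen were a term for the 2 arrays with low signal in the 24 poly-A spike-in probe sets, and DBP replicates 1 and 2, or 3 and 4, against vehicle, and camera with an estimated correlation in the model with that term. The 18 hybridisation spike-in probe sets served as a comparison. The labels name no labelling or hybridisation batch.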

Results

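Testes of Fischer rat fetuses at gestational day 20 were profiled on 8 Affymetrix rat expression arrays. In 4 samples the dams had received corn oil vehicle, and in 4 they had received 50 mg/kg of dibutyl phthalate (DBP), a plasticizer known at high doses to lower testosterone production by the fetal testis. Dosing was daily by gavage from day 12 to day 20 of gestation, with tissue taken 6 h after the last dose. The comparison asked which testis transcripts differed between the exposed and the vehicle fetuses at this dose. Median log2 values of the arrays lay between 6.08 and 6.13, correlations across probe sets between any pair of arrays lay between 0.991 and 0.998, and the RNA integrity number was 8.6 to 8.8. The labels do not say that samples came from separate dams or litters, so the p-values measure only the spread between these samples, and the number of arrays limits the precision. DBP replicates 3 and 4 stood apart in the poly-A spike-ins, bacterial transcripts added to the RNA before labelling, whose mean log2 signal was 4.84 and 4.79 against 6.46 to 7.17 on the other 6 arrays. Their SD over all log2 values was also lower, 2.19 and 2.18 against 2.23 to 2.25. Values for the 2 DBP arrays without low spike-in signal, replicate 1 (7.17, above the vehicle arrays) and replicate 2 (6.68), are therefore given for the largest changes and for the lists that passed, and values with the spike-in level as a term where it ended or gained a list member's call.

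The largest increases after DBP included genes of secreted factors and a receptor. Stc1, which encodes the secreted hormone stanniocalcin 1, rose 3.20-fold, from a log2 value of 6.79 ± 0.071 to 8.47 ± 0.47 (SD, n = 4 per group; adjusted p = 0.00377). Nppc, the precursor of C-type natriuretic peptide, rose 3.18-fold (log2 change 1.67 ± 0.23, SE; adjusted p = 0.00919), and Smpx, a small protein of striated muscle, rose 3.15-fold (1.66 ± 0.15; adjusted p = 0.0013). Gnrhr, the receptor for gonadotropin-releasing hormone, rose 3.08-fold (1.62 ± 0.18; adjusted p = 0.00377). Sfn, which encodes 14-3-3 sigma, rose 2.51-fold (adjusted p = 0.00132). Testin, a secreted product of Sertoli cells, rose 2.46-fold (adjusted p = 0.0112), and Nr4a1, the orphan nuclear receptor Nur77, rose 2.24-fold (adjusted p = 0.0132). Of the other 5 largest rises, Chchd4l1 (0.97 on the log2 scale), Ass1 (0.95), Hao2 (0.91), Srxn1 (0.89) and Grb14 (0.83), Ass1 encodes argininosuccinate synthetase of the urea cycle, Hao2 a peroxisomal hydroxyacid oxidase and Srxn1 sulfiredoxin. Both other probe sets of Stc1 and the other probe set of Gnrhr also rose. Neither of the 2 dimmer ones of Srxn1 passed (0.30 and 0.08), and the mean over its probe sets was 0.42. In DBP replicates 1 and 2 against vehicle the changes were 1.39 for Stc1 (1.97 in replicates 3 and 4), 1.58 for Nppc, 1.55 for Smpx, 1.64 for Gnrhr, 1.34 for Sfn, 1.22 for Testin and 1.06 for Nr4a1. They were 0.89 for Chchd4l1, 0.91 for Ass1, 1.02 for Hao2, 0.95 for Srxn1 and 0.82 for Grb14.

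The decreases were smaller. Ccnd2, which encodes the G1 cyclin D2, had the largest, -0.90 ± 0.16 on the log2 scale (SE; 1.87-fold lower, adjusted p = 0.032), from 11.54 ± 0.071 to 10.64 ± 0.41 (SD, n = 4 per group), with DBP replicate 2 lowest at 10.03. That rank rested on 1 array: without DBP replicate 2 the change was -0.70, against -0.91 for Greb1, and Ccnd2 lost its call without any 1 of the vehicle arrays (adjusted p up to 0.122), without DBP replicate 1 (0.0533) or without DBP replicate 3 (0.0523). Greb1, an estrogen-responsive gene, changed by -0.85 ± 0.092 (adjusted p = 0.0034) and Gadd45g, a stress-response gene with a role in mouse testis determination, by -0.81 ± 0.10 (adjusted p = 0.0065). Cacna1h, a T-type calcium channel subunit, changed by -0.78, Naglu, a lysosomal enzyme of heparan sulfate breakdown, by -0.72, Ano1, a calcium-activated chloride channel, by -0.71, and Tgfa, a ligand of the EGF receptor, by -0.70. Lratd1 (-0.79), LOC100911253 (-0.78), Adgra1 (-0.76), Shisa8 (-0.69) and Prmt8 (-0.68) made up the rest of the 12 largest falls. The second probe sets of Tgfa and Shisa8 fell as well. A dimmer probe set of Cacna1h lay higher by 0.23 without passing (adjusted p = 0.186), and the mean over both probe sets of that gene gave -0.27 (adjusted p = 0.113); a dimmer one of Greb1 gave 0.05, with a mean of -0.40. Neither of the 2 other probe sets of LOC100911253 passed (-0.24 and -0.19), and the mean over its probe sets was -0.41. In DBP replicates 1 and 2 against vehicle the changes were -1.12 for Ccnd2 (-0.68 in replicates 3 and 4), -0.78 for Greb1, -0.67 for Gadd45g, -0.79 for Cacna1h, -0.64 for Naglu, -0.58 for Ano1 and -0.65 for Tgfa. They were -0.70 for Lratd1, -0.84 for LOC100911253, -0.55 for Adgra1 (-0.97 in replicates 3 and 4), -0.71 for Shisa8 and -0.66 for Prmt8.

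**Figure D1:**
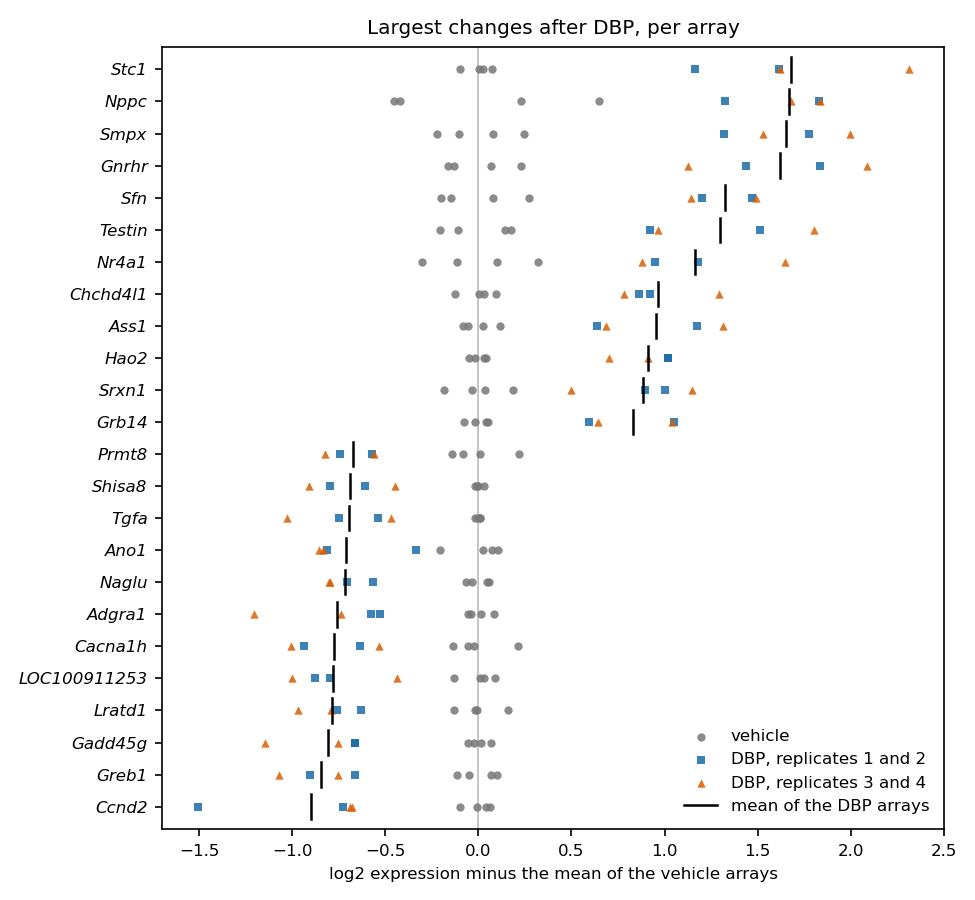
Log2 expression of the 12 genes with the largest rise and the 12 with the largest fall, each as the difference from the mean of the 4 vehicle arrays, 1 point per array, with the mean of the 4 DBP arrays as a bar. Genes were chosen among those with all 4 DBP points on 1 side of all 4 vehicle points; DBP replicates 1 and 2 are squares and replicates 3 and 4 triangles, and Ccnd2 in replicate 2 lies apart.

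In all, 331 of 31042 probe sets passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05, with 130 higher and 201 lower after DBP, while 5664 had an unadjusted p under 0.05. After each array was shifted to the same median the split was 158 higher and 159 lower of 317. Most changes were small: among the 174 genes whose representing probe set passed, 85 higher and 89 lower, 123 differed by less than 1.5-fold, and 19 probe sets differed by at least 2-fold. The groups did not overlap for any of these 174 genes, nor for 3379 of all probe sets, where chance gives 2.86% of them. Replicates 1 and 2 against vehicle gave 577 probe sets, 243 of them among the 331, and replicates 3 and 4 gave 4129, with 330 of the 331. With low spike-in signal as a term 438 passed, 201 of them among the 331. Of the 24 genes with the largest changes 23 kept an adjusted p under 0.05, the exception being Ano1 (-0.58 with the term, adjusted p = 0.0688). Only DBP replicates 3 and 4 carry that term, so the change it leaves is that of replicates 1 and 2 against vehicle. The 24 genes were also chosen on these arrays, so their calls with the term are no separate check. Unmoderated t statistics gave 74 probe sets and kept 4 of the 24 genes, Smpx, Sfn, Hao2 and Naglu. The count fell when any 1 vehicle array was left out, to 114, 122, 82 and 118 without vehicle replicates 1, 2, 3 and 4. It was 248, 606, 220 and 374 without DBP replicates 1, 2, 3 and 4. Without vehicle replicate 3, 10 of those 24 genes (Testin, Nr4a1, Ass1, Srxn1, Ccnd2, LOC100911253, Cacna1h, Adgra1, Ano1 and Tgfa) had an adjusted p above 0.05, up to 0.122. Calls also ended for Ccnd2, Adgra1, Ano1 and Tgfa without vehicle replicate 1 (up to 0.109), for these and Ass1 without vehicle replicate 2 (up to 0.0844). They ended for Ass1, Srxn1, Ccnd2, Adgra1 and Tgfa without vehicle replicate 4 (up to 0.0804), for Ccnd2 and Ano1 without DBP replicate 1 (up to 0.0611) and for Ccnd2, Adgra1 and Ano1 without DBP replicate 3 (up to 0.0704).

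Genes of steroid hormone synthesis, the best known target of DBP in the fetal testis, did not pass at this dose. Star, which carries cholesterol into mitochondria, averaged 10.81 ± 0.14 in vehicle and 10.91 ± 0.15 after DBP (SD, n = 4 per group), a log2 change of 0.10 with a 95% confidence interval of -0.10 to 0.30. The change was 0.12 for Scarb1, the HDL receptor (-0.10 to 0.33), -0.13 for Cyp11a1, the side-chain cleavage enzyme (-0.26 to 0.01), -0.05 for Cyp17a1 (-0.21 to 0.12) and 0.17 for Hsd3b1 (0.05 to 0.30; adjusted p = 0.163). Of 13 measured genes of the list, 0 passed in limma over all probe sets and 0 when adjusted over the list alone. An unadjusted p under 0.05 was seen for 4: Hsd3b1, Fdx1 and Hsd17b3 higher, and Hsd17b1 lower (-0.35). Unmoderated t statistics also gave 0 past the threshold. In all, 174 of 14217 genes passed in limma and 5664 of 31042 probe sets had an unadjusted p under 0.05, so a short list with 0 past says little. Insl3, the Leydig cell hormone of testis descent, was lower in all 4 DBP arrays, with a change of -0.34 ± 0.077 (SE) that missed the threshold (adjusted p = 0.0732; with the spike-in term -0.41 and 0.0608). Of the 9 measured Leydig cell markers 0 passed over all probe sets, 5 had an unadjusted p under 0.05, and the same 5 passed when adjusted over the list alone. These were Insl3, Vsnl1 (-0.70), Lhcgr, the luteinizing hormone receptor (-0.21), and Prlr (-0.38) lower, and Hsd11b1 (0.28) higher. Prlr was named after its value was seen.

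**Figure D2:**
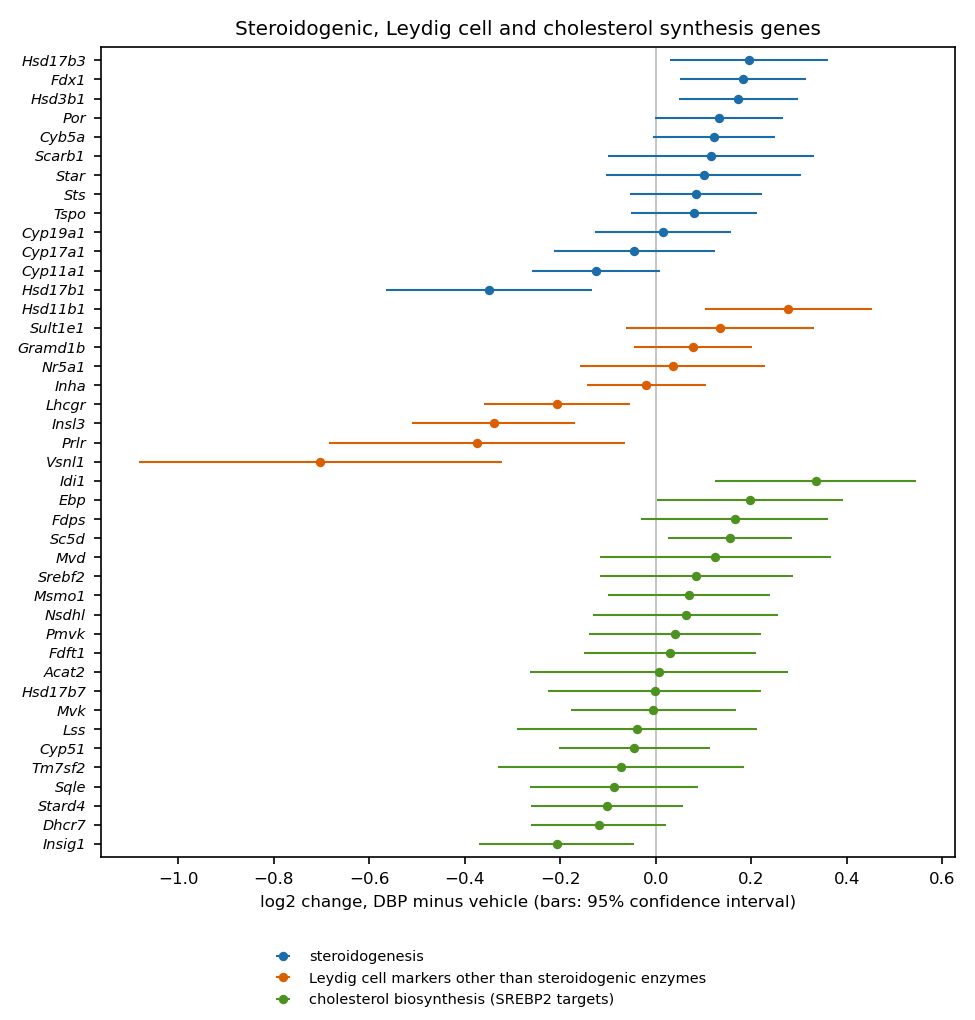
Log2 change of each measured gene of 3 lists, DBP minus vehicle, with its 95% confidence interval from limma (4 arrays per group). Most intervals of steroidogenic and cholesterol synthesis genes include 0, and those of Insl3, Vsnl1, Lhcgr and Prlr lie below it.

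Few genes of the lipid lists passed over all probe sets, as few did among all genes (174 of 14217). Lipid genes outside these lists that passed are given under other observations. Of 20 cholesterol synthesis genes 0 passed in limma, over all probe sets or adjusted over the list alone, and 4 had an unadjusted p under 0.05, among them Idi1 (0.34, adjusted p = 0.121) and Insig1 (-0.21, adjusted p = 0.191). Among 17 genes of cholesterol uptake, storage and export, 1 fell: Nceh1, a neutral cholesterol ester hydrolase, changed by -0.56 ± 0.094 (SE, adjusted p = 0.0235; with the spike-in term -0.43 and 0.0612). Nceh1 lost its call without any 1 of the vehicle arrays (adjusted p up to 0.102). Adjusted over the list alone, Lipa, the lysosomal acid lipase, also passed, higher by 0.28. Of 15 fatty acid synthesis genes 0 passed over all probe sets and 6 had an unadjusted p under 0.05, and adjusted over the list alone Fads2 (0.38) and Scd (0.49) were higher and Elovl6 (-0.21) lower. Phthalate esters are known to activate PPAR alpha in liver. Of 24 genes of fatty acid oxidation and PPAR alpha response 0 passed over all probe sets, which says little where so few of all genes did. An unadjusted p under 0.05 was seen for 6, of which 4 were higher, such as Ucp3 and Acot2 (0.21 each), and 2 lower. Adjusted over that list alone, Cpt1a (-0.26) and Fabp3 (-0.29) were lower. Unmoderated t statistics gave 0 in each of these lists.

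Among 19 transcription regulators of steroidogenesis, Nr4a1 rose and Cebpa, a leucine zipper factor, fell by 0.51 on the log2 scale (adjusted p = 0.015; 0.0416 with the spike-in term), and 3 of its 4 other probe sets fell too. Adjusted over the list alone, Ppargc1a also passed (0.29). Of 28 immediate early genes, 1 rose, Nr4a1, and 1 fell, Egr2 (-0.37, adjusted p = 0.0298), whose other probe set was higher by 0.15 without passing; the mean over its probe sets was -0.11 (adjusted p = 0.319). Adjusted over the list alone, Nr4a3, a close relative of Nr4a1, also passed, higher by 0.96 ± 0.20 (SE; adjusted p over all probe sets = 0.0548). Fos (0.02), Egr1 (-0.06), Dusp1 (0.01) and Nr4a2 (-0.03), chosen after their values were seen, did not pass. In limma 9 of the 28 immediate early genes had an unadjusted p under 0.05, 5 higher and 4 lower. Of 9 heat shock genes Hspe1, the mitochondrial co-chaperonin, rose by 0.31 (adjusted p = 0.0224; with the spike-in term 0.28 and 0.0547), and its partner Hspd1 gave 0.12 (adjusted p = 0.252); adjusted over the list alone 1 passed, Hspe1. Among 23 genes of xenobiotic metabolism and oxidative stress, Srxn1 rose 1.85-fold (adjusted p = 0.0126) and Hmox1, heme oxygenase 1, fell by 0.37 (adjusted p = 0.032). Adjusted over the list alone Gstp1 (0.23) and Cyp1b1 (0.29) were also higher. Nqo1 (-0.01), Gclc (0.15), Gclm (0.09) and Txnrd1 (-0.07), chosen after their values were seen, did not pass. Of the 23 genes 8 had an unadjusted p under 0.05 in limma, 6 higher and 2 lower. Unmoderated t statistics ended the calls of Nr4a1, Cebpa, Egr2, Srxn1 and Hmox1, with 0 past the threshold among the regulators, immediate early and xenobiotic genes and 1 among the heat shock genes. Without any 1 of the vehicle arrays, Cebpa, Egr2, Hspe1 and, except without vehicle replicate 4, Hmox1 lost their calls, with adjusted p up to 0.126. So did Egr2 and Hmox1 without DBP replicate 3 (0.0736 and 0.0599) and Hmox1 without DBP replicate 1 (0.0719).

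Markers of testis cell types mostly did not pass. Amh, the Sertoli cell hormone of Müllerian duct regression, changed by -0.05 ± 0.073 (SE, n = 4 per group; adjusted p = 0.749). Of 15 Sertoli cell markers 0 passed over all probe sets and 8 had an unadjusted p under 0.05; adjusted over the list alone Aard (0.24) and Cst12 (0.46) were higher and Inhbb, the inhibin beta B subunit (-0.35), lower. With the spike-in term 1 passed, Gata1, which also acts in erythroid cells (0.59, adjusted p = 0.018, against 0.36 and 0.182 without the term); its values were 5.83, 5.55, 5.19 and 5.26 in DBP replicates 1 to 4 and 5.10 on average in vehicle. Of 8 germ cell markers 0 passed, with 2 at an unadjusted p under 0.05, and Sycp3 (0.31) was higher adjusted over the list alone. Of 12 peritubular myoid markers 0 passed by either adjustment and 4 were higher at an unadjusted p under 0.05. Plvap, of the endothelial diaphragm, rose by 0.36 (adjusted p = 0.0471; with the spike-in term 0.27 and 0.125) as 1 of 13 endothelial markers. Of 18 macrophage and immune markers 0 passed over all probe sets and 3 had an unadjusted p under 0.05; Fcer1g (0.27) and Cd74 (0.24) were higher adjusted over the list alone. Of 10 erythroid markers 0 passed and 1 had an unadjusted p under 0.05, Hba-a3 (0.28), which passed adjusted over the list alone; the list's median was 0.40 in DBP replicates 1 and 2 and -0.03 in replicates 3 and 4. With the spike-in term 3 of them passed, Slc4a1 (1.26, adjusted p = 0.0111), Alas2 (0.70, adjusted p = 0.0286) and Hemgn (0.63, adjusted p = 0.0362), against 0.45, 0.28 and 0.32 without it. Slc4a1 and Alas2 were named after their values were seen. Of 12 mesonephric duct and epididymis markers 0 passed by either adjustment and 2 had an unadjusted p under 0.05. Of 7 adrenal markers, Mrap, an accessory protein of melanocortin receptors, fell by 0.61 (adjusted p = 0.029; with the spike-in term -0.61 and 0.0612), and adjusted over the list alone Th and Dbh were also higher and Chga lower. Unmoderated t statistics gave 0 in each of these marker lists. Plvap and Mrap lost their calls without any 1 of the vehicle arrays (adjusted p up to 0.142 and 0.116), Plvap also without DBP replicate 3 (0.0999) and Mrap without DBP replicate 1 (0.0671).

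**Figure D3:**
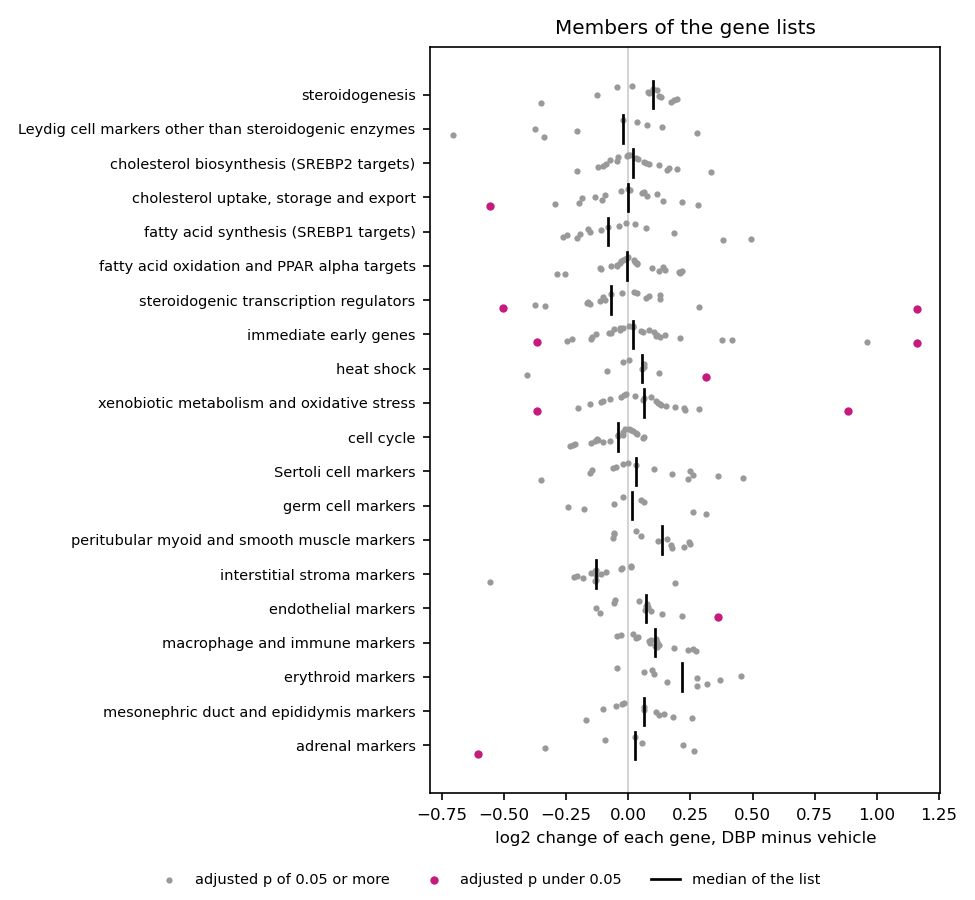
Log2 change of each measured member of the 20 gene lists, DBP minus vehicle, with each list's median as a bar and larger points for an adjusted p under 0.05. Medians lie between -0.13 and 0.22, and single members such as Nr4a1 and Srxn1 stand apart from the rest of their lists.

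Tested as whole lists with camera, 2 of 20 passed at a preset correlation of 0.01, stroma and cell cycle, and neither did with an estimated correlation (adjusted p = 0.707 for each with an estimated correlation). The 17 interstitial stroma markers had a median change of -0.13 (adjusted p = 0.0433), with 14 of them lower, Postn (-0.56) among them. The 21 cell cycle genes had a median of -0.04 (adjusted p = 0.0471), with 14 lower. In both lists 0 members passed over all probe sets. An unadjusted p under 0.05 was seen for 3 stroma genes, 2 lower and 1, Mgp (0.19), higher, and for 4 cell cycle genes, all lower. Adjusted over the list alone 0 stroma genes passed, and 3 replication licensing genes, Mcm2 (-0.24), Mcm5 (-0.21) and Mcm6 (-0.22), were lower. The median was -0.05 for stroma and -0.01 for cell cycle in DBP replicates 1 and 2 (adjusted p = 0.387 and 0.296), against -0.18 and -0.12 in replicates 3 and 4 (adjusted p = 0.00396 and 0.028). Without DBP replicate 3 the adjusted p was 0.0695 for stroma and 0.0552 for cell cycle, without DBP replicate 4 it was 0.0633 and 0.134, without vehicle replicate 4 it was 0.0635 for both, and without vehicle replicate 3 it was 0.0766 for cell cycle. The number of lists passing was 4 without vehicle replicate 2, 1 without vehicle replicate 3, and 0 without vehicle replicate 4 or DBP replicate 3. Without DBP replicate 4 it was 3, none of them stroma or cell cycle but the macrophage, erythroid and myoid markers, upward (adjusted p = 0.00668, 0.0258 and 0.027). With array weights it was also 3, stroma with the macrophage and erythroid markers (adjusted p = 0.0259, 0.0219 and 0.0231), while cell cycle was lost (adjusted p = 0.0564). Among the remaining 18 lists the adjusted p ranged from 0.0616, for macrophage and immune markers (median 0.11), to 0.988; with the spike-in term those markers, the erythroid markers and the peritubular myoid markers passed upward at the preset correlation (adjusted p = 0.00895, 2.15e-07 and 0.0275) but not with that term and an estimated correlation (adjusted p = 0.622, 0.535 and 0.622 with an estimated correlation). The test's direction was down where the median was above 0 for the immediate early genes and the adrenal markers, and where it was 0.00 for cholesterol uptake.

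**Figure D4:**
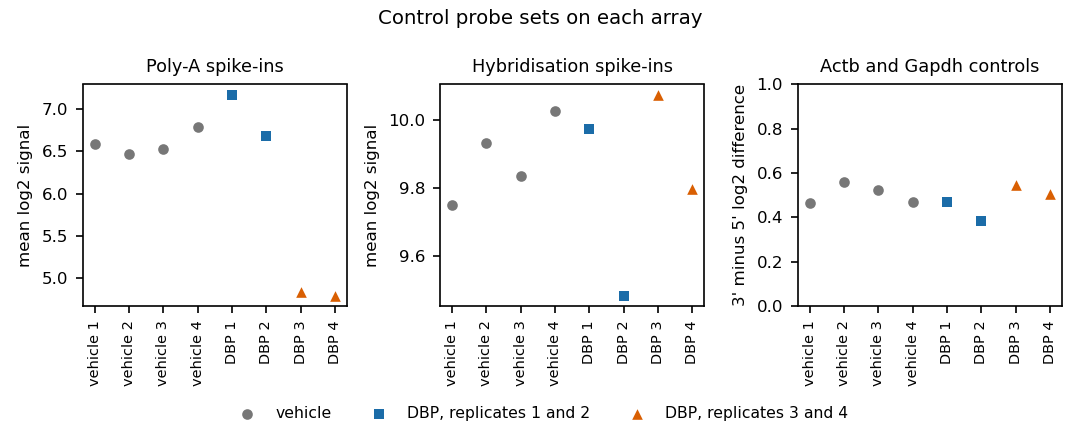
Mean log2 signal of the poly-A spike-ins and of the hybridisation spike-ins, and the 3' minus 5' log2 difference of the Actb and Gapdh control probe sets, 1 point per array. DBP replicates 3 and 4 lie at 4.84 and 4.79 for the poly-A spike-ins and at 10.08 and 9.80 for the hybridisation spike-ins, where the other arrays span 9.48 to 10.03.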

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

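Chosen only after the result was seen were the tests on the spike-ins and RNA controls, on pairs of DBP arrays, on the cell cycle and stroma lists against the spike-in level, and on the muscle genes in DBP replicates 1 and 2. The real grouping gave 331 probe sets past the threshold. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many, the real one, and the highest other gave 0. The real split always counts, so 1 of 35 is the least this test can give. It argues against a chance split as the source of the count but cannot exclude it. For the gene lists, 18 of the 35 splits gave as many as the 2 passing lists and the highest other gave 5, so chance cannot be excluded there either.

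In 7 cases a sample stood apart from the other 3 of its group, by the gap to the nearest sample as a share of the range, among 222 groups of values examined, where chance gives about 1 in 20. Ccnd2 was 10.03 in DBP replicate 2 against 10.81 to 10.86 (gap share 0.94). Ano1 was 7.73 in DBP replicate 2 against 7.21 to 7.25 (0.923). Cyp1b1 was 10.96 in DBP replicate 2 against 10.60 to 10.66 (0.833). Mcm5 was 8.71 in vehicle replicate 1 against 8.85 to 8.87 (0.875), and 8.66 in DBP replicate 1 against 8.59 to 8.60 (0.857). Sycp3 was 9.17 in vehicle replicate 1 against 8.92 to 8.95 (0.88), and Mov10l1 was 6.78 in vehicle replicate 2 against 7.09 to 7.15 (0.838).

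In the control probe sets, which entered no comparison, DBP replicates 3 and 4 had low poly-A spike-in signal (a mean of 4.81 against 6.70) and a larger 3' minus 5' difference of these spike-ins (2.07 against a mean of 1.19). Weaker hybridisation predicts low hybridisation spike-ins, but these were higher by 0.10 on the 2 arrays, and degraded sample RNA predicts a larger 3' minus 5' difference of Actb and Gapdh, which differed by 0.0458, within the other arrays' range. A separate labelling batch stays open: 16 probe sets passed between DBP replicates 1 and 2 and replicates 3 and 4, against 0 in either other pairing of the 4 arrays, and in the model of all 8 arrays 1172 (413 higher, 759 lower) differed between these pairs of arrays. The erythroid list was lower in DBP replicates 3 and 4 than in 1 and 2 (adjusted p = 3.46e-05 with camera at the preset correlation). A difference in blood content between the samples therefore stays open beside a labelling batch. In vehicle replicates 1 to 4 Ahsp was 8.09, 8.13, 7.53 and 7.61. Hba-a3 was 11.75, 11.86, 11.58 and 11.59, and Hemgn 5.48, 5.65, 5.31 and 5.27. For these genes replicates 3 and 4 were thus lower on vehicle arrays too, without low spike-in signal. Ank1 (6.19, 6.32, 6.17 and 6.47) went otherwise. DBP replicates 3 and 4 may have been labelled apart, or have received less spike-in. Other differences between the fetuses were not tested. No vehicle array had low signal, so a batch could be weighed only within the DBP group.

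For the lower cell cycle and stroma lists, the unadjusted camera p for DBP replicates 3 and 4 against 1 and 2 was 0.0313 and 0.00163, and the adjusted p 0.209 and 0.0163. The mean change of the stroma list against vehicle was -0.08, 0.01, -0.19 and -0.21 in DBP replicates 1 to 4, and that of the cell cycle list -0.03, -0.02, -0.05 and -0.14, with replicate 4 apart. In replicates 1 and 2 against vehicle the unadjusted p was 0.213 for stroma and 0.119 for cell cycle. A labelling batch may account for the stroma list, while for cell cycle it cannot be told apart from a difference of replicate 4 alone, as the difference between the pairs of arrays did not pass when adjusted. An effect of DBP of differing size between samples was not tested.

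Smpx (1.66), Myom2 (0.79), Ldb3 (0.56) and Tnni1 (0.40) encode proteins of striated muscle and rose; the last 3 were named after their values were seen. Carried-over skeletal muscle would bring its abundant transcripts, yet the 16 measured muscle markers, listed before their values were seen, had a median change of 0.096. It lay below 0.201, which is 0.5 times the smallest of the 4 changes, with 0 markers past the threshold in limma. The SE of 0.022 across markers treats genes on the same arrays as independent. Over arrays, the SE of single markers was 0.060 (Myog) to 0.125 (Chrna1). Some markers were dim, such as Acta1 (3.69 in vehicle) and Mb (3.70). Tnnc1, whose probe set gave the highest signal of the 16 markers, went from 9.03 to 9.12, though signals of different probe sets do not rank abundance. With the spike-in term 2 of the 4 genes, Smpx and Tnni1, kept an adjusted p under 0.05, a count that decided nothing about a labelling batch. In that model the changes were 1.55, 0.80, 0.55 and 0.30 for Smpx, Myom2, Ldb3 and Tnni1. They rest on DBP replicates 1 and 2, and each lay at least 4.39 SE from 0 (the least for Ldb3). The genes were picked by their calls on these same arrays. All 331 called probe sets kept more than 0.5 times their change in DBP replicates 1 and 2. The choice of genes thus set this result, and it cannot decide about a batch on replicates 3 and 4 as the whole cause. A response of testis cells to DBP may explain the rises and was not tested.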

How the results depend on the processing

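Chosen only after the data were seen were the spike-in term, also with an estimated correlation, and the fits of 2 DBP arrays against vehicle. The count of 331 probe sets (130 higher, 201 lower) stayed within 1.5 times under the signal filters (375 and 376), shifted medians (317), quantile normalization (348), trend and robust prior (463), RNA integrity (368), array weights (468), removal of cross-matching probe sets (301) and the spike-in term (438). With the filter at the median (15520 probe sets tested) 231 of the 331 calls were kept. RNA integrity kept 234, the spike-in term 201 and each other setting named here at least 289. The count was thus steadier than the calls behind it. It moved to 92 (45 higher, 47 lower) with a 1.5-fold minimum, 820 (329, 491) at an adjusted p under 0.1, 74 (41, 33) with unmoderated t statistics, 577 (211, 366) for DBP replicates 1 and 2 and 4129 (2004, 2125) for replicates 3 and 4; with 1 probe set per gene 132 were lower. Leaving out 1 array gave 82 to 606 (42 to 235 higher, 40 to 371 lower) and 0 to 4 lists. With the replicate block it was 175 (65 higher, 110 lower) and 1 list. After each group's mean was removed per probe set, same-numbered arrays correlated at 0.11, -0.08, 0.10 and -0.02. Vehicle replicates 1 and 3 matched the same-numbered DBP array best, while 2 and 4 did not, so pairing by number was not settled. The number of lists was 1 with shifted medians, quantile normalization or no cross-matching probe sets (stroma). It was also 1 with the filter at the median (macrophage, not 1 of the original 2) and with RNA integrity (erythroid, likewise). It was 0 with the filter at 5, fry's directional test, or an estimated correlation with or without the spike-in term. The cause of these moves was not tested. Over 2195 pairs of a named gene and an alternative 0 calls reversed; these pairs leave out the other thresholds, unmoderated t statistics and 1 probe set per gene. Of the 24 genes with the largest changes 14 passed throughout these pairs, but unmoderated t statistics kept 4 of the 24; Insl3 passed in 6 of 21 (adjusted p from 0.0211 to 0.202). How far signal over background limits dim probe sets was not measured.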

Other observations

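Chosen only after the values were seen were all genes of this part, which the rule for naming genes did not reach, and no test of a family or pathway was run on them. Of 15 measured aldo-keto reductase genes 3 rose, Akr1b8 by 0.76 (adjusted p = 0.00153), Akr1b7 by 0.54 (adjusted p = 0.0049) and Akr1c19 by 0.43 (adjusted p = 0.0149), and 0 were lower past the threshold in limma. Gatm (0.69), Got1 (0.59) and Kyat3 (0.31) rose, and the amino acid transporter genes Slc7a8 (-0.65) and Slc7a7 (-0.39) and the folate enzyme gene Shmt1 (-0.43) fell. Hsd11b2, which inactivates glucocorticoids, changed by -0.61 (adjusted p = 0.003). Ch25h, the cholesterol 25-hydroxylase (0.66), Mgll (0.65), Acsl4 (0.62) and Hpgd (0.48) rose. Stc2, a relative of Stc1, changed by -0.58 in the opposite direction (adjusted p = 0.00746), Pdgfa by -0.38 and Cdt1 by -0.39. Ramp1, a partner of the calcitonin receptor-like receptor, rose by 0.64 and Rerg by 0.74. With the spike-in term 19 of 26 genes kept an adjusted p under 0.05. The other 7 fell without the term and missed the threshold with it, with changes of -0.39 and -0.31 for E2f2 (adjusted p = 0.103 with the term), -0.30 and -0.27 for Cdca7 (0.0618), -0.38 and -0.31 for Fanca (0.13), -0.34 and -0.29 for Aldh1l1 (0.0953), -0.34 and -0.26 for Bhmt (0.107), -0.39 and -0.42 for Nrg1 (0.0593), and -0.28 and -0.29 for Arsa (0.0592).

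The mean change of the erythroid markers against vehicle was 0.51, 0.43, -0.01 and -0.09 in DBP replicates 1 to 4, and that of the cholesterol synthesis genes was -0.01, 0.12, 0.16 and -0.15.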
